A study of Mus musculus with 32 samples.

How the data were processed

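Total RNA from the hippocampus of 16 male mice, 6 to 8 weeks old, was hybridised to exon arrays, 1 array per mouse. 8 mice were Sicd2-ISCL4 subcongenics and 8 were FVB-like littermates. Each array appears as 2 samples, 1 summarised per gene and 1 per exon probe set, so the 32 samples are 16 arrays and the exon-level values are not further replicates. Group and replicate number were taken from the sample titles. The labels' protocols state that both hippocampi of each mouse were combined, so a replicate is a mouse.

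The values the authors deposited are on the log2 scale. Per the submitters' processing notes, RMA, Partek 6.6 and build mm9 were used, with the role of each not given in the sources used here. RMA generally corrects background, equalises the distributions of arrays and reports probe set signal on the log2 scale. No detection call was used here, so a dim value can be background. There are 16755 features at gene level and 188590 probe sets at exon level. At gene level, 14996 features carried 1 gene symbol, 1019 several and 740 none. At exon level the numbers were 179269, 1325 and 7996. Symbols came from the platform annotation and were matched to RefSeq genes of assembly GRCm38.p6, which included all 14996 single symbols of the gene level and 178913 of the exon level. That assembly differs from the files' build, so it gave names, chromosomes and the order of genes, and no coordinates.

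The array files named in the labels follow 2 naming schemes. Replicates 1 to 4 of both groups share one scheme (array set A) and replicates 5 to 8 the other (array set B), giving 4 mice per group in each set. What separates the sets is not stated in the labels. Array set entered every fit as a covariate. The values were fitted with limma (lmFit and eBayes; limma 3.58.1, R 4.3.3, statmod 1.5.0), and features with a Benjamini-Hochberg adjusted p under 0.05 over all features of that level were called. All adjusted p values of single genes and probe sets are limma's. Differences are ISCL4 minus FVB-like on the log2 scale, with the standard error of the fit, and group values are mean ± SD over 8 mice. The number of arrays limits the precision: the median standard error of a gene's difference was 0.062, or 1.04-fold. Figures were drawn with matplotlib.

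Calls were counted per chromosome and compared with all other chromosomes by a two-sided Fisher's exact test over 20 chromosomes. The counts are of features with 1 symbol, 14996 for 14847 symbols, since some genes have more than 1 feature. Clusters of neighbouring calls were sought in windows of 20 such features. The highest number of calls in a window was compared with 10000 random placements of the calls over all chromosomes. Exon usage was tested with limma's diffSplice on probe sets at or above the 25th percentile of mean signal, in genes with at least 3 such probe sets, and summarised per gene by the Simes method. Gene lists, 31 in all, covered receptors and channels, stress and metabolic pathways and markers of the cell types and neighbouring tissues a hippocampal sample can hold. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the lists. A list needed at least 5 measured members. An exact permutation test of each list's mean, over all 4900 exchanges of group labels within array sets, was added after the data were examined.

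Groups, designs, lists and most alternatives were fixed before the data were examined, as was the rule for naming genes. Named genes had 1 symbol, an adjusted p under 0.05 and the same direction in both array sets, and were the 15 largest increases, the 15 largest decreases, up to 20 called genes of chromosome 15 and up to 15 called list members. The 4 members with the smallest p of each list that passed, the 6 genes with the smallest adjusted p for exon usage, and values of members of the glutamate receptor, apoptosis and immediate early lists were also allowed. Any other gene named was chosen after its values were seen.

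The steps named in this paragraph were tested on simulated data built from the real arrays with known changes. Camera with an estimated correlation, fry, the exact permutation tests, Fisher's test by chromosome and the replicate block were not simulated. In the simulated gene-level comparison of 16755 features, 46% of 50 features changed by 1.2-fold were recovered, 92% at 1.5-fold, 100% at 2-fold and 96% at 3-fold, with 8 false calls. At exon level, among 188590 probe sets, recovery was 0%, 40%, 76% and 96%, with 6 false calls. The list test recovered 28 of 31 lists shifted by 1.1-fold, with 0 false calls. The simulated genes varied independently, whereas estimated correlations within the real lists reached 0.90. The simulation therefore cannot show how often camera at the preset correlation falsely calls a list of correlated genes. The window test found the 1 simulated cluster among 14996 genes. The exon usage test recovered 10%, 78%, 100% and 100% of changed genes but also gave 340 false calls among 11601 genes, so its count is too high. A version that uses each probe set's own spread was therefore added after the data were examined. In the same simulation it recovered 2%, 58%, 88% and 96%, with 6 false calls.

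The replicate numbers of the groups were checked for pairing. Deviations from the group means of mice with the same number correlated across genes at 0.30 to 0.49 in all 8 pairs, above the limit of 0.1 set for treating them as paired. Part of this came from array set: with it removed, the correlations ran from -0.05 to 0.25, and 6 of the 8 were above 0.1. The labels do not say what a shared number means. The replicate number was therefore also used as a block in place of array set, and blocked values are given where the block changed the call of a gene, probe set or list. Calls that hold only without the block are less certain. The block with an estimated correlation, with fry, with the exact test (over all 256 exchanges within pairs) and with each probe set's own spread was added after the data were examined.

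Alternatives covered leaving out array set, using it as a random block, using each set alone, the replicate block, quantile normalization, centring on the median, other variance estimates, array weights, filters on dim features, a minimum of 1.2-fold, and leaving out each array in turn. Genomic sequence, probe sequences and genotypes of the mice were not used here.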

Results

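Gene expression in the hippocampus was measured in 16 mice, 8 of the Sicd2-ISCL4 subcongenic line (ISCL4 mice) and, as controls, 8 of their FVB-like littermates. Sicd2 is a chromosome 15 locus for susceptibility to seizure-induced cell death, and a subcongenic carries a shortened donor segment of such a locus on the host strain, so the comparison asks which transcripts differ with that segment. All mice were male, and the labels record no seizure or other treatment. Array medians lay between 7.29 and 7.34 on the log2 scale at gene level and between 7.74 and 7.78 at exon level. Pairs of arrays correlated at 0.973 to 0.995 across genes. No 2 arrays held identical values. The first principal component, with 36.7% of the variance, separated array set A from array set B, and 7771 genes differed between the sets, while each set held 4 mice of each group.

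The largest difference between the groups was in Fgf1, which encodes acidic fibroblast growth factor. Fgf1 (transcript cluster 6864837, chromosome 18) had a log2 signal of 8.92 ± 0.32 (SD, n = 8) in ISCL4 mice and 7.25 ± 0.11 (SD, n = 8) in littermates, a rise of 1.67 (SE 0.091), or 3.19-fold, with limma's adjusted p = 9.99e-08. Zfp706, a zinc finger protein gene of chromosome 15, rose 1.87-fold at gene level, from 8.64 ± 0.19 to 9.54 ± 0.19 (adjusted p = 3.43e-06). Its 2 exon probe sets moved in opposite directions, by 2.21 and -0.41, so only 1 of them carried this rise. Trhr, the receptor for thyrotropin-releasing hormone, rose 1.58-fold (adjusted p = 0.0135). Among the genes that fell, 6 belonged to the beta protocadherins, neuronal cell adhesion molecules encoded side by side on chromosome 18. Pcdhb3 had the largest decrease, from 8.70 ± 0.22 to 7.81 ± 0.34, a log2 difference of -0.89 (SE 0.094, adjusted p = 0.000295).

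Activity-regulated transcripts were among the other increases. Egr2, an immediate early transcription factor, rose by 0.59 (SE 0.097, adjusted p = 0.0185). Arc, a regulator of synaptic AMPA receptors, rose by 0.51 (adjusted p = 0.0157) and Nr4a1, a nuclear receptor of the immediate early class, by 0.48 (adjusted p = 0.0129), and both lie on chromosome 15. Ptgs2, the inducible cyclooxygenase, rose by 0.36 (adjusted p = 0.0262) and Inhba, the activin A subunit, by 0.35 (adjusted p = 0.0276). Rnf14, an E3 ubiquitin ligase, Aldh7a1, the lysine catabolism enzyme, and Ndufa2, a subunit of respiratory complex I, all of chromosome 18, rose 1.46-fold, 1.44-fold and 1.29-fold. In Rnf14 the rise was largest at 1 exon probe set, at 4.39, with a median of 0.13 for the others. Alox12b rose 1.35-fold (adjusted p = 0.00617) and Klf17 1.28-fold. The bitter taste receptor gene Tas2r130 rose 1.55-fold, at a dim signal of 4.65 in ISCL4 mice.

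The other beta protocadherins that fell were Pcdhb6 (-0.72), Pcdhb8 (-0.53), Pcdhb11 (-0.50), Pcdhb4 (-0.43) and Pcdhb2, which went from 8.32 ± 0.06 to 7.90 ± 0.15. Pcdhb11 was read by 2 gene-level features, and the other differed by -0.03 (adjusted p = 0.947). Over the whole family, examined after these values were seen, 19 of 23 features, which stand for 22 genes, had lower values in ISCL4 mice, with a median of -0.17, and the count was 19 with quantile normalization or median centring too. These genes are paralogs, and probes can pick up more than one of them, so the level of each is uncertain. Outside the family, Lrrtm4, a postsynaptic organiser of excitatory synapses, fell by 0.29 (SE 0.043, adjusted p = 0.0077). Tspan2, a tetraspanin of the oligodendrocyte lineage, fell by 0.42 (adjusted p = 0.0345). Gpcpd1, the G protein subunit gene Gng13, the extracellular matrix link protein gene Hapln1 and Selenof fell by 0.31, 0.29, 0.26 and 0.22. Minar2 and Mro of chromosome 18 fell by 0.27 and 0.25. N4bp2l2 fell by 0.24 at gene level, but its 3 exon probe sets differed by only -0.08 to -0.01. Of these, 0 had an unadjusted p under 0.05, so no exon probe set showed the fall.

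In all, 49 of 16755 gene-level features passed, 28 higher and 21 lower in ISCL4 mice, and 46 of them carried 1 symbol. An unadjusted p under 0.05 was reached by 2414 features, against 838 by chance. All 49 had the same direction in both array sets, which is likely for features called on both sets together. The groups did not overlap for 20 of the 16755 features, where chance gives 0.016% or 2.6 features, and 16 of the 20 were among the 49. Most changes were small: the median size was 0.32, or 1.25-fold, and 1 gene exceeded 2-fold. Within array sets, of 4 against 4 mice, 0 features passed in set A and 5 in set B, and the test of a different effect in the sets called 1 feature, which was not one of the 49.

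With the replicate number as a block, 18 features passed at gene level, 16 of them among the 49. Under that block, limma's adjusted p lay between 0.0517 and 0.109 for 23 of the 36 genes that the naming rule gave and that passed without it. Those described above were Trhr, Aldh7a1, Arc, Ndufa2, Ptgs2, Klf17, Inhba, Pcdhb8, Tspan2, Gpcpd1, Gng13, Minar2, Hapln1, Mro, N4bp2l2 and Selenof.

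**Figure D1:**
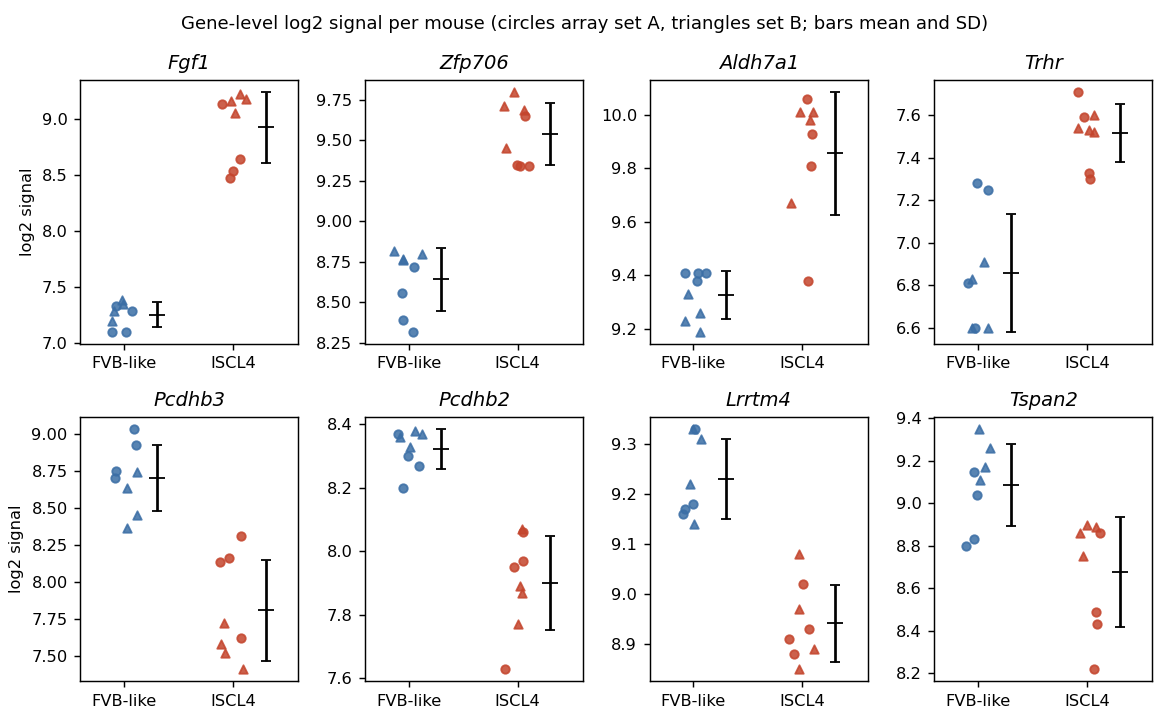
Gene-level log2 signal of each mouse for 8 genes, with FVB-like littermates in blue and ISCL4 mice in red, circles for array set A, triangles for array set B, and bars for the mean and SD of 8 mice. Fgf1 averaged 7.25 in littermates and 8.92 in ISCL4 mice with no overlap, whereas 1 ISCL4 mouse had an Aldh7a1 signal of 9.38, within the range of the littermates.

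Because the Sicd2 locus lies on chromosome 15, calls were counted by chromosome. On chromosome 15, 9 of 575 features with 1 symbol, counted here as genes, passed: Zfp706, Trhr, Arc, Nr4a1, Angpt1, Rspo2, Drosha and Pdgfb were higher and Cdh12 lower. Angpt1, the angiopoietin-1 gene, rose by 0.36 (SE 0.068), the Wnt agonist gene Rspo2 by 0.32 (SE 0.054), Drosha, the nuclear microRNA processing enzyme, by 0.29 (SE 0.041) and the growth factor gene Pdgfb by 0.23 (SE 0.044). The cadherin gene Cdh12 fell by 0.21 (SE 0.039, adjusted p = 0.0345). The share of 1.57% compared with 0.257% elsewhere, an odds ratio of 6.2 (95% interval 2.6 to 13.1, Fisher's exact test, two-sided p = 5.21e-05, adjusted p = 0.000521 over 20 chromosomes). This excess did not pass with the replicate number as a block, where 2 genes of chromosome 15 were called (Fisher's exact p = 0.111).

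Chromosome 18 held more calls than chromosome 15. There, 14 of 363 genes passed, 5 higher and 9 lower, a share of 3.86% against 0.219% elsewhere (odds ratio 18.3, 95% interval 8.9 to 35.6, exact p = 2.2e-12, adjusted p = 4.4e-11). Fgf1, Rnf14, Aldh7a1, Ndufa2 and Mbd1, a methyl-CpG binding protein gene, were higher, and the 6 beta protocadherins, Minar2, Mro and Ndfip1 were lower. Mbd1 and Ndfip1, named here after their values were seen, differed by 0.33 and -0.20, the latter with adjusted p = 0.0751 under the replicate block. On the remaining chromosomes 23 of 14058 genes passed, or 0.164%.

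Windows of neighbouring genes passed on both chromosomes. The placements were drawn over all chromosomes, so a chromosome with more calls passes more easily. The window p values therefore partly restate the chromosome shares and do not by themselves show that calls cluster within a chromosome. One window of 20 measured features on chromosome 18, from Tmco6 to Pcdhb11, held 7 called genes, Ndufa2 and the 6 protocadherins (permutation p = 0.0001, the smallest the placements can give, adjusted p = 0.002). The placements, like Fisher's test of this chromosome, count the 6 paralogs as independent calls. Probes can pick up more than one of them, so these p values may be too small. On chromosome 15 the window from Zfp706 to Rspo2 held 3, Zfp706, Angpt1 and Rspo2 (permutation p = 0.0035, adjusted p = 0.035). No other chromosome passed. With the replicate number as a block, 2 genes passed on chromosome 15 (Fisher's exact p = 0.111, adjusted p = 1) and 8 on chromosome 18 (adjusted p = 1.21e-08), and 1 cluster passed, that of chromosome 18. Drosha, Rspo2, Angpt1, Pdgfb and Cdh12 were among the genes that lost the call under the block, with limma's adjusted p of 0.0683, 0.0526, 0.109, 0.0808 and 0.108.

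**Figure D2:**
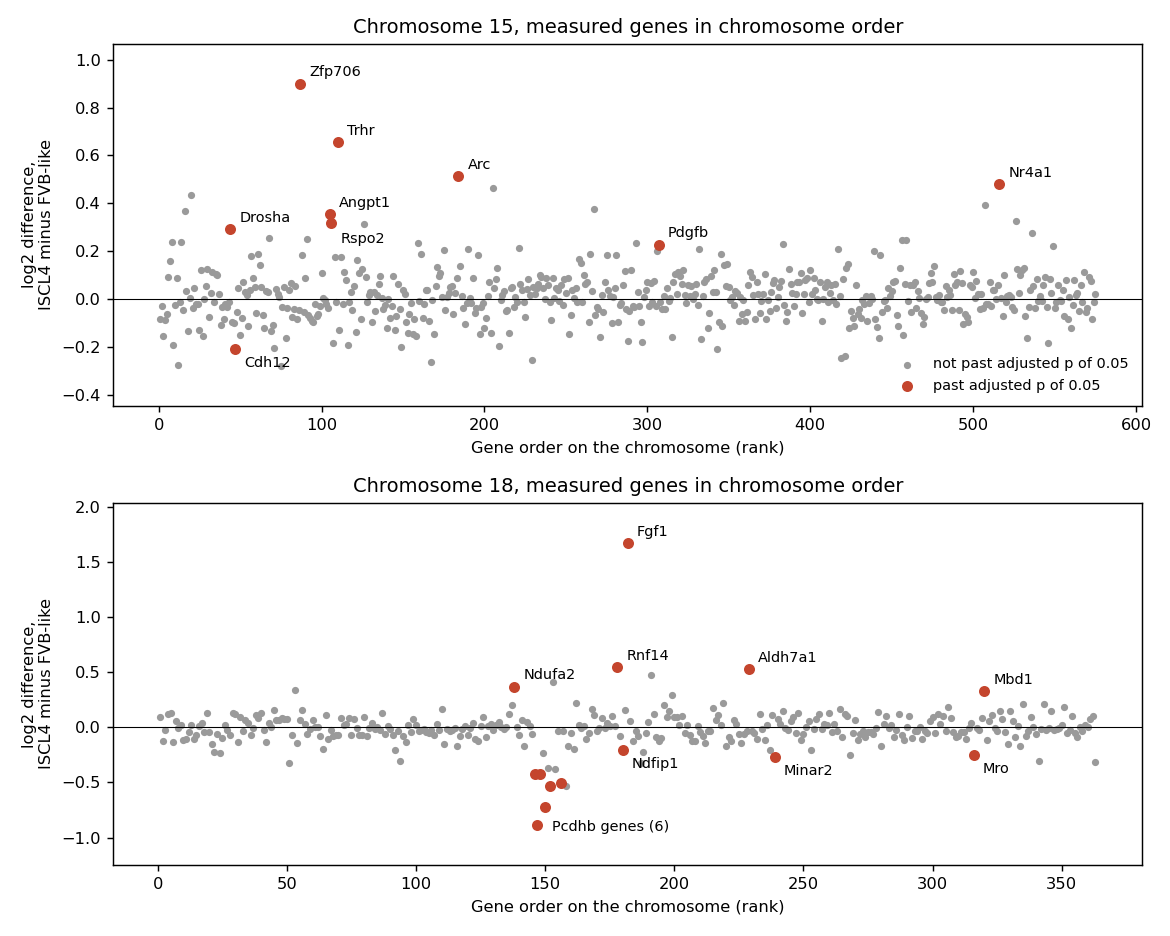
Log2 difference between ISCL4 and FVB-like mice for each measured gene-level feature of chromosomes 15 and 18, in gene order of assembly GRCm38.p6 (rank, not distance), with called genes in red. On chromosome 15, 6 of the 9 calls lie between ranks 44 and 110 of 575, and 7 of the 14 on chromosome 18 fall in one window of 20 features.

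Single exon probe sets were compared to see which parts of the transcripts differed. Fgf1 was higher in ISCL4 mice at all 9 of its probe sets, and 7 of these passed, with differences of 1.84 to 2.23, while the other 2 differed by 0.36 and 0.42. All 6 probe sets of Pcdhb3 were lower, from -1.50 to -0.32, and 3 passed, 1 of them with the replicate number as a block. Aldh7a1 was higher at 20 of 21 probe sets, Nr4a1 at 12 of 12 and Trhr at 5 of 5. Other genes differed most at 1 probe set. In Rnf14, probe set 4791470 went from 4.88 ± 0.60 in littermates to 9.27 ± 0.37 in ISCL4 mice, a difference of 4.39 (SE 0.236, adjusted p = 3.3e-07), while the others had a median difference of 0.13. Probe set 5449024 of Rnf14 passed too, at 0.72 (adjusted p = 7.75e-05), and 6 of its 11 probe sets were higher with an unadjusted p under 0.05.

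Similar contrasts within a gene were seen on chromosome 15. The leading probe set of Drosha rose by 2.63 against a median of 0.23 for the others, of which those at 1.16 and 0.77 passed too. Of its 41 probe sets 37 were higher in ISCL4 mice, 22 with an unadjusted p under 0.05. The leading probe set of Rspo2 rose by 1.96 against 0.12, and that of Rad21, a cohesin subunit gene, by 1.34 against -0.04. Zfp706 was read by 2 probe sets, which moved in opposite directions, 2.21 and -0.41, and both passed. On chromosome 18 the leading probe set of Mbd1 rose by 2.16 against 0.17, with another called at 1.16, and that of Kcnn2, a small-conductance calcium-activated potassium channel gene, by 1.35 against -0.14. The leading probe sets of Drosha and Kcnn2 and the lower probe set of Zfp706 lost their calls with the replicate number as a block, with limma's adjusted p of 0.163, 0.0567 and 0.142. The Drosha probe set at 0.77 kept its call (adjusted p = 0.00989) and those at 1.16 in Drosha and Mbd1 did not (0.144 and 0.0504).

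Over the exon-level table, 47 of 188590 probe sets passed, 37 higher and 10 lower, and 19303 had an unadjusted p under 0.05 against 9430 by chance. Of the 44 with an assigned chromosome, 13 lay on chromosome 15 in 9 genes, 25 on chromosome 18 in 14 genes and 6 elsewhere. When each gene was represented by the median of its probe sets, 9 of 15796 genes passed. With the replicate number as a block, 30 probe sets passed, and 2 genes by the median of their probe sets.

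Differential exon usage was called by the diffSplice test in 718 of 11612 genes, 45 of 493 on chromosome 15 and 58 of 316 on chromosome 18. The 6 genes with the smallest p were Rnf14 (adjusted p = 2.55e-82), Drosha (1.04e-61), Mbd1 (6.12e-36), Rad21 (2.34e-35), Rspo2 (1.04e-21) and Kcnn2 (3.85e-19). This count is too high, since the test gave 340 false calls on simulated data. With each probe set's own spread, added after the data were examined, limma called 22 genes, 8 on chromosome 15, 11 on chromosome 18 and 3 elsewhere. All 6 named genes were among the 22, with adjusted p of 3.59e-08 for Rnf14, 0.0287 for Drosha, 0.000661 for Mbd1, 0.00205 for Rad21, 5.05e-05 for Rspo2 and 0.0134 for Kcnn2. With the replicate number as a block, diffSplice called 1084 genes, and the test with each probe set's own spread no longer called Drosha (adjusted p = 0.108). Fgf1, added here after its values were seen, was called by both tests, with adjusted p = 8.08e-12 by diffSplice and 4.75e-07 with each probe set's own spread (2.19e-05 under the replicate block), and its leading probe set by diffSplice, 5326008, rose by 0.36 against a median of 2.02 for the others.

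**Figure D3:**
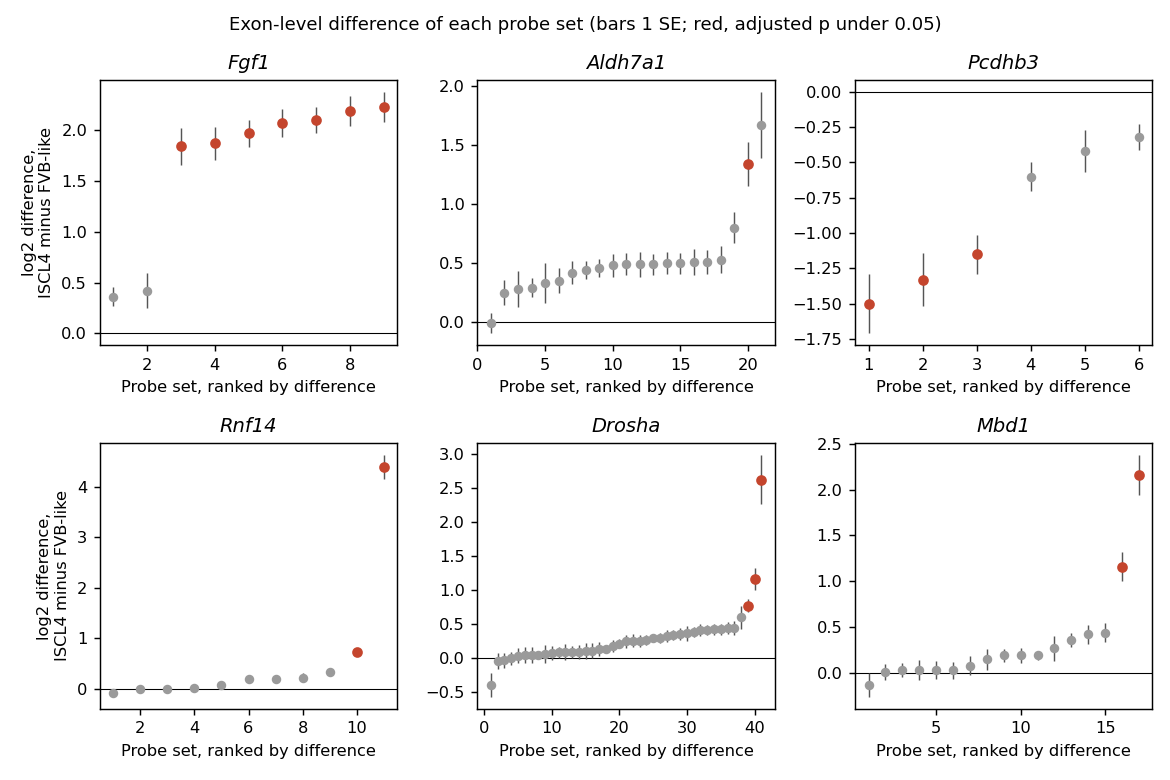
Log2 difference between ISCL4 and FVB-like mice at each exon probe set of 6 genes, ranked by size within the gene, with bars of 1 SE and called probe sets in red. Fgf1 was higher at all 9 probe sets, 7 of them by 1.84 to 2.23 and 2 by 0.36 and 0.42, whereas in Rnf14 1 probe set differed by 4.39 and the median of the others was 0.13.

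Gene lists fixed before the data were examined were then compared as groups. The activity-dependent immediate early genes rose together: 18 of 20 measured members had higher values in ISCL4 mice, with a mean difference of 0.225, and 4 passed over all genes, Egr2, Arc, Nr4a1 and Nr4a3. Adjusted over the list alone, 11 passed, all higher. Fos, Fosl2 and Dusp1 had differences of 0.39, 0.35 and 0.33 and did not pass over all genes, and Jun and Klf4 had -0.01 each. The adjusted p was 9.1e-11 by camera, 0.0318 with an estimated correlation and 0.00041 by fry. The exact permutation test within array sets gave p = 0.000408, the smallest possible, and adjusted p = 0.0127 over the 31 lists. The mean difference was 0.182 in array set A and 0.268 in array set B, and all 8 ISCL4 mice lay above the mean of the littermates of their set. Arc and Nr4a3 lost their calls with the replicate number as a block (limma's adjusted p = 0.0517 and 0.108), and Egr3 lost that over the list alone (0.0574). The list then had adjusted p = 1.05e-09 by camera, 0.00227 by fry and adjusted p = 0.103 with an estimated correlation. The exact test over exchanges within pairs gave p = 0.00781, the smallest possible, and adjusted p = 0.0807. Over 31 lists, a list at this smallest p passes only if several others reach it too, so the adjusted p cannot decide. The immediate early list also differed by 0.416 between the array sets, B minus A.

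Markers of oligodendrocytes, the myelinating cells, had lower values in 14 of 15 measured members, with a mean difference of -0.226. Among them Aspa, Mal, Mog and Cldn11 differed by -0.48, -0.40, -0.37 and -0.35, whereas Mbp and Trf, which encode abundant myelin basic protein and transferrin, differed by 0.02 and -0.02. The list fell by camera (adjusted p = 2.83e-07), with adjusted p = 0.568 with an estimated correlation. No member passed over all genes, and 6 passed when adjusted over the list alone, all lower. The exact permutation p was 0.0139, or 0.143 when adjusted over the lists. The mean difference was -0.245 in array set A and -0.206 in array set B. In set A, FVB-like replicates 2 and 3 had means of 0.436 and 0.375, against -0.088 to 0.121 in the other littermates, and without either one the list kept its call by camera, at -0.193 (adjusted p = 5.67e-06) and -0.202 (adjusted p = 5.39e-06). FVB-like replicate 2 also had the highest mean of markers of striatum, 0.861 against at most 0.276 in the other mice.

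Markers of meninges and fibroblasts had lower values in all 14 measured members, with a mean of -0.146, and the list passed by camera (adjusted p = 0.0074) but had adjusted p = 0.826 with an estimated correlation. Ogn, Igf2, Col1a2 and Col1a1 differed by -0.33, -0.29, -0.21 and -0.13, and 0 members passed over all genes or adjusted over the list alone. Genes of GABA signalling had a mean of -0.060 (camera adjusted p = 0.0417), with adjusted p = 0.568 with an estimated correlation. Gabrb2, Gabra4, Gabra2 and Gabra5, receptor subunits for inhibitory transmission, differed by -0.16, -0.15, -0.14 and -0.12, and 0 members passed over all genes or adjusted over the list alone. In all, camera called 4 of 31 lists, and of these lists only the immediate early genes were called with an estimated correlation, by fry or by the exact test within array sets. With the replicate number as a block camera called 5, the same 4 and oxidative phosphorylation, which had a mean of -0.047 (adjusted p = 0.0265, against 0.0558 without the block), and 0 lists were called with an estimated correlation. The GABA list was lower in the ISCL4 mouse of all 8 pairs, and the exact test within pairs gave p = 0.00781 and adjusted p = 0.0807. These equal the values of the immediate early genes only because both lists lie at the smallest p possible.

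Apoptosis genes and ionotropic glutamate receptors, which bear on cell death after seizures, were not called. Of 31 apoptosis genes 0 passed over all genes and 0 adjusted over the list alone, with a mean of -0.003 and camera's adjusted p = 0.739. Birc3 and Fas had 0.22 and 0.24, and Bcl2l2 and Xiap -0.16 each, with unadjusted p under 0.05 for each of them. Of 14 ionotropic glutamate receptor genes 0 passed over all genes, with camera's adjusted p = 0.146. Adjusted over the list alone, 1 passed: the kainate receptor gene Grik2, at -0.15, joined by Grin2c, at 0.15, with the replicate number as a block (adjusted p = 0.023). Other lists held 2 called members, Ndufa2 of oxidative phosphorylation (list adjusted p = 0.0558) and Fezf2, a transcription factor of deep-layer cortical neurons, which rose by 0.22 in the list of neocortex and subiculum (list adjusted p = 0.886). Neither gene kept its call with the replicate number as a block, where limma's adjusted p was 0.0617 for Ndufa2 and 0.0751 for Fezf2.

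**Figure D4:**
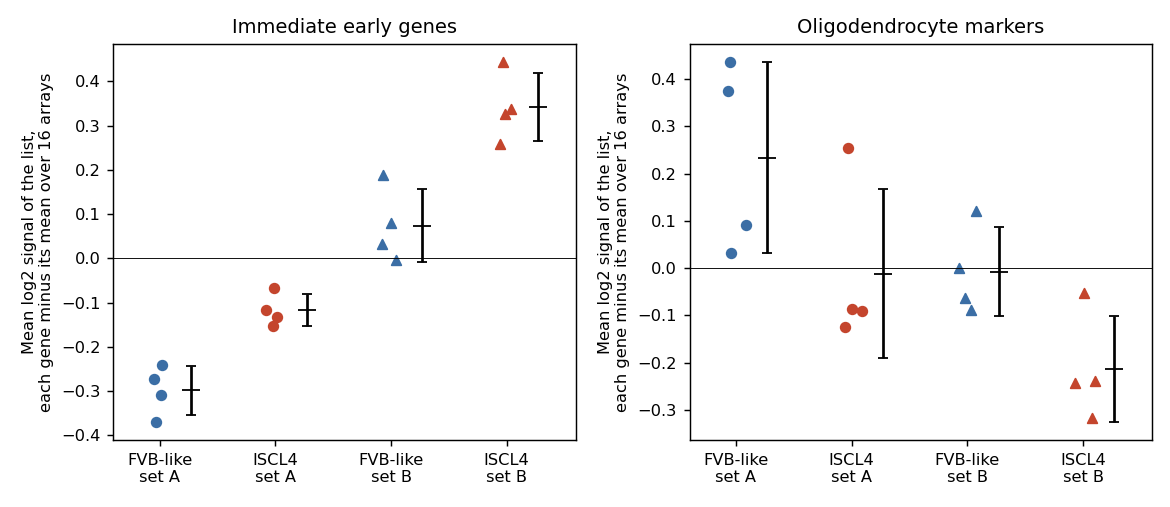
Mean log2 signal per mouse of the immediate early genes and of the oligodendrocyte markers, each gene taken relative to its mean over 16 arrays, for FVB-like (blue) and ISCL4 (red) mice of each array set, with bars for the mean and SD of 4 mice. The immediate early genes were higher in ISCL4 mice by 0.182 in set A and 0.268 in set B, and 1 ISCL4 mouse of set A stands above the others in the oligodendrocyte markers.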

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

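All the tests of explanations in this part, and the counts over other splits of the arrays, were chosen or given their criteria after the results were seen.

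In 6 of 104 groups of 8 mice, 1 mouse lay far from the others, where chance gives about 1 in 20. FVB-like replicate 5 had an Rnf14 signal of 11.17 against 10.91 to 11.01 in the others, a gap of 0.601 of the range of its group. ISCL4 replicate 3 had a Selenof signal of 10.10 against 10.26 to 10.36 (gap 0.613 of the range). FVB-like replicate 4 had a Gabra4 signal of 9.52 against 9.86 to 10.09 (gap 0.596). ISCL4 replicate 1 had a Mog signal of 10.72 against 9.91 to 10.26 (gap 0.566), a mean of the oligodendrocyte markers of 0.25 against -0.32 to -0.05 (gap 0.537) and a mean of the GABA signalling genes of 0.04 against -0.05 to -0.02 (gap 0.611).

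The clustering of called genes on chromosomes 15 and 18 was weighed first. A difference at 1 probe set alone was argued against for 18 of the 23 called genes, Fgf1 and Arc among them. The median of their other probe sets kept at least 50% of the difference, with limma's unadjusted p under 0.05. That p was 2.53e-12 for Fgf1, but 0.032 for Pcdhb11, 0.0165 for Cdh12 and 0.0157 for Ndfip1. The genes were called on the same arrays, and variants under several probes of a gene were not examined. In 2 more of the 23, Rnf14 and Mbd1, another probe set passed in the same direction, at 0.72 and 1.16. Limma's adjusted p was 7.75e-05 and 0.0156, or 0.0106 and 0.0504 with the replicate number as a block. The median of their other probe sets differed by 0.22 and 0.15, under 50% of the gene-level 0.55 and 0.33. More than 1 probe set thus differed, in Mbd1 only without the block, but 1 probe set as the source of most of the difference was not excluded. The remaining 3 were Zfp706, Rspo2 and Pcdhb8. Of the 2 probe sets of Zfp706, 5600078 rose by 2.21 and 5100333 differed by -0.41, so only 1 carried the gene-level rise. For Rspo2 and Pcdhb8 a difference at 1 probe set alone stays open. Without the leading probe set they differed by 0.14 and -0.16, under 50% of the gene-level 0.32 and -0.53. In all 3, a variant under a probe and a change in 1 exon cannot be told apart, since both give the same values. Among genes of these chromosomes with exactly 1 called probe set, 12 were higher and 3 lower in ISCL4 mice (exact binomial p = 0.0352). With the replicate number as a block 11 were higher and 3 lower (exact binomial p = 0.0574). On the other chromosomes 6 were higher and 0 lower (Fisher's exact p = 0.53, a comparison chosen after these counts were seen). With 0 lower there, no larger share of increases could appear on chromosomes 15 and 18, so the comparison cannot decide. Whether probes that match the donor sequence better than the FVB sequence gave these increases stays open. Donor segments in the ISCL4 mice, on chromosome 15 by design and on chromosome 18 as a hypothesis (the related locus Sicd1 lies there), are the biological explanation and were not tested, because genotypes were not used here.

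The rise of the immediate early genes was weighed second. Array set is balanced over the groups by design. The position of Arc and Nr4a1 on chromosome 15 was argued against by a mean of 0.194 without the chromosome 15 members (camera adjusted p = 5.99e-08; 5.85e-13 to 0.103 over 28 alternatives of the whole list). Handling of the mice before the tissue was taken cannot be told apart from genotype: these genes respond within minutes to handling, the list differed by 0.416 between array sets, and the labels record no handling. A genotype effect stays open and untested.

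The lower oligodendrocyte markers were weighed last, and array set is balanced here too. Less myelinated tissue in the ISCL4 samples cannot be told apart from a change in the cells: with the mean of the other members in the fit, 1 of 15 members kept a genotype difference, Trf, which was then higher in ISCL4 mice by 0.17, while Mbp differed by 0.02 without that term. ISCL4 replicate 1 lay above the other ISCL4 mice on this list, and FVB-like replicates 2 and 3, at 0.436 and 0.375, lay above the other littermates (-0.088 to 0.121). FVB-like replicate 2 was also high for markers of striatum (0.861, against at most 0.078 in the other littermates) and of thalamus and habenula (0.387, against at most 0.116), and the oligodendrocyte difference was -0.193 without it and -0.202 without FVB-like replicate 3. A genotype effect stays open and untested.

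Chance assignment of arrays to groups was examined with 100 splits, the real one included. For the 49 genes, 1 split, the real one, gave as many, and the highest other gave 1, and for the 47 exon probe sets it was 1 split, with a highest other of 1. Chance can be excluded for these counts, which come from the fits without the replicate block. For the 9 genes of chromosome 15 and the window of 7 called neighbours it was also 1 split each, with a highest other of 0, but as the other splits called at most 1 gene, these restate the gene count and are no separate exclusion. For the 718 genes of the exon usage test 3 splits gave as many, with 1291 and 875 genes in the others. Other groupings can thus exceed the real count, and the test gave 340 false calls on simulated data, so chance is not excluded for it. For the 4 lists 48 splits gave as many, with a highest of 12, so chance cannot be excluded for the number of lists. Among 100 of the 128 splits that, like the real one, part all 8 pairs of replicate numbers, the highest others were 1 gene, 1 gene of chromosome 15, 1 exon probe set and 426 genes of exon usage, and 56 splits gave 4 or more lists.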

How the results depend on the processing

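The setting without both arrays of replicate 4 (farthest from their groups on the first principal components), the lists without chromosomes 15 and 18, the counts on chromosome 18, the exon usage test with each probe set's own spread, and the replicate block combined with it, with fry or with an estimated correlation were chosen after seeing the data. Among the genes of the naming rule and the 4 lists called by camera, no difference changed sign under any alternative. This is little support, since they were chosen on the same arrays. For called genes the naming rule already required the same direction in both array sets. Some of the other lists did change sign. The heat shock proteins, not called with both sets, had a mean of 0.114 in array set A and -0.076 in set B (camera adjusted p = 0.0439 and 0.0443). Without array set the fit called 15 genes, 4 on chromosome 15, 23 exon probe sets, 85 genes for exon usage and 1 cluster. With array set as a random block it called 29 genes. Set A alone gave 0 genes (0 on chromosome 15), 1 exon probe set and 219 genes for exon usage, and set B alone 5 genes, 2 on chromosome 15 and 13 exon probe sets, with fewer mice in each. The replicate block gave 18 genes, 2 on chromosome 15, 30 exon probe sets, 1084 genes for exon usage and 1 cluster, ended the call of 23 of the 36 called genes that the naming rule gave, and gave 5 lists, the 4 of the fit without it and oxidative phosphorylation. With an estimated correlation it left 0 lists, with fry 1 list, and with each probe set's own spread 28 genes for exon usage. eBayes with trend and robust estimation gave 102 genes, 49 higher and 53 lower, and 273 exon probe sets, 145 higher and 128 lower, against 37 and 10. An ordinary linear model gave 74 genes, 43 higher and 31 lower. Features at or above the 25th percentile gave 84 genes, 42 each way, and 99 exon probe sets, 65 higher and 34 lower, and those at or above the median 178 genes, 74 higher and 104 lower, and 223 exon probe sets, 121 higher and 102 lower, with fewer features tested; the share of chromosome 15 then had Fisher's exact p = 0.154. A minimum of 1.2-fold left 32 genes. Quantile normalization gave 26 genes higher and 12 lower, against 28 and 21. Without both arrays of replicate 4 there were 25 genes, 5 on chromosome 15, and 29 exon probe sets. The F test called 439 genes for exon usage, and each probe set's own spread 22. An estimated correlation left 1 list and fry 1 list. Over 28 alternatives, the immediate early list lost its call in 1, the replicate block with an estimated correlation (adjusted p = 0.103), and the oligodendrocyte, meningeal and GABA lists lost theirs in 4, 6 and 17. Except where fewer mice or features were used, the cause was not tested. Leaving out 1 array gave 19 to 66 genes, 5 to 10 on chromosome 15, 26 to 47 exon probe sets, 371 to 929 genes for exon usage and 2 to 7 lists. The gene count was 25, 31, 28 and 21 without FVB-like replicates 2, 3, 5 and 7, and 26, 28, 24, 31 and 19 without ISCL4 replicates 2, 3, 6, 7 and 8. Chromosome 15 had 5 genes without FVB-like replicate 7 or ISCL4 replicate 8, and chromosome 18 had 8, 9 and 8 without FVB-like replicate 7, ISCL4 replicate 6 or ISCL4 replicate 8. Exon probe sets numbered 26 without FVB-like replicate 8 and 29 without ISCL4 replicate 7. Exon usage was called in 391, 371 and 406 genes without FVB-like replicates 5 or 7 or ISCL4 replicate 8. Without ISCL4 replicates 1, 4 or 5 there were 7, 2 and 7 lists. Fgf1, Zfp706, Pcdhb3, Rnf14, Egr2, Arc and Nr4a1 were among the genes that kept their calls through all 16 of these fits. Other named genes lost theirs in most of the fits. Hapln1 and Fezf2 lost the call in 14, and Angpt1, Pdgfb, Gpcpd1, Gng13 and Selenof in 13. Cdh12, Nr4a3 and Minar2 lost it in 12, and Tspan2, Klf17 and Tas2r130 in 11. Without a measure of background, signal near it could not be set apart.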

Other observations

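The values in this part were read after the main results, and the genes outside the naming rule were chosen after their values were seen.

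Principal cell markers of the hippocampus were not called as groups by camera. Markers of dentate granule cells, CA1 pyramidal cells, and CA3 and CA2 pyramidal cells had mean differences of -0.058, 0.039 and -0.011 (camera adjusted p = 0.146, 0.477 and 0.726). The dentate granule cell list was lower in the ISCL4 mouse of all 8 pairs of equal replicate numbers (exact test within pairs, p = 0.00781, the smallest possible, adjusted p = 0.0807 over 31 lists), but had adjusted p = 0.176 by camera with the replicate number as a block. Within the CA3 and CA2 list, members went both ways: adjusted over the list alone, Nptx1 and Amigo2 were higher, at 0.17 and 0.20, and Nectin3 lower, at -0.20. Interneuron markers had a mean of 0.047 (adjusted p = 0.0603). Astrocyte and microglia markers had 0.003 and 0.031 (adjusted p = 0.911 and 0.886).

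Circadian clock genes also differed in opposite directions within the list, whose mean was 0.006 (camera adjusted p = 0.911). Adjusted over the list alone, Per1, Nfil3 and Bhlhe40 were higher, at 0.21, 0.35 and 0.18, and Dbp and Rorb lower, at -0.34 and -0.15, of which Bhlhe40 and Rorb did not pass with the replicate number as a block (limma's adjusted p = 0.0688 each). Per1 is also a member of the immediate early list. None of the 16 measured members passed over all genes in limma, although 5 had an unadjusted p under 0.05.

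Choroid plexus markers varied together more than any other list, with an estimated correlation of 0.90, and their mean in ISCL4 mice ran from -0.876 in replicate 8 to 0.95 in replicate 1. The list's difference between the groups was -0.161 (camera adjusted p = 0.244). Markers of striatum, a neighbouring tissue, had a mean of -0.158 (adjusted p = 0.11), which was -0.051 (adjusted p = 0.548) without FVB-like replicate 2. The choroid plexus difference lay between -0.302 without ISCL4 replicate 1 (adjusted p = 0.00856) and -0.057 without ISCL4 replicate 8 (adjusted p = 0.76).

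In 1 ISCL4 mouse, replicate 3, Aldh7a1 was 9.38, against 9.67 to 10.06 in the other ISCL4 mice and 9.19 to 9.41 in the littermates. At the Fgf1 probe sets 5326008 and 4847146, which did not pass, the groups differed by 0.36 and 0.42, against 1.84 to 2.23 at the other 7. Probe set 4815846 of Eif2s3y, a gene of the Y chromosome, was 0.99 higher in ISCL4 mice (limma's adjusted p = 0.0463, or 0.144 with the replicate number as a block). Of its other probe sets, 4697284 differed by 1.38 (adjusted p = 0.0666), 4559572 by -0.49 (adjusted p = 0.49) and the remaining 12 by -0.19 to 0.17.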
